A study of Escherichia coli and Bacillus subtilis with 8 samples.

How the data were processed

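NET-seq captures the nascent RNA bound to RNA polymerase and sequences its 3' ends. Per the labels' protocols, cultures of 500 mL were grown at 37 °C to an optical density of 0.45, filtered, frozen and milled, polymerase was recovered through a FLAG tag, and the RNA 3' ends were ligated to an adapter before sequencing. E. coli MG1655 grew in rich defined medium with glucose and B. subtilis 168 in LB. Of the 8 samples, pause lists of the 2 wild-type NET-seq libraries were analysed here. The other 6 samples, 5 E. coli NET-seq libraries (deletions of the elongation factor genes greA and greB, and bicyclomycin treatment) and 1 E. coli RNA-seq library, were not analysed here, so no comparison of those conditions was made.

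The authors deposited for each library a list of pause sites with a whole-number score per site. Bowtie 0.12.7 and CASAVA are named in the submitters' processing notes. The pause caller, its threshold, the genome build, the annotation and the counting base of positions are not given in the sources used here. The meaning of the score is not given either. It depends on the named gene, since 12 of the 13 E. coli positions listed under 2 genes, and 25 of 30 in B. subtilis, carried differing scores, so it was used only to rank sites within a list. The scores are not read counts, and the depth per sample is unknown, so all intervals cover the number of listed sites only.

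The listed position was taken as base 15 of each 30-nt sequence. All 5886 pairs of overlapping neighbours in E. coli and all 1826 in B. subtilis agreed in sequence. Such agreement shows only a constant offset along the strand and would be found whichever base was the listed one. Only 2 opposite-strand overlaps, both in E. coli, bore on the base and the strand, and they gave base 15. For B. subtilis the base was carried over without such a check. That it marks the RNA 3' end is an assumption. Symbols were used as given. No genome of the builds used was at hand. The reference gene table of assembly ASM584v2 was used for E. coli names only, because 18.9% of the listed positions fell inside the reference gene of that name. Of 2668 E. coli symbols, 2423 matched directly, 238 through a synonym and 7 not at all, and 2584 of 4290 protein-coding genes (60.2%) had a site. A B. subtilis symbol whose sites lay over 10000 nt apart was split, which gave 2030 loci.

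Base shares were computed for each position with exact binomial 95% intervals. Without a genome, the fallback set before the data were examined was used as background, the outermost 3 positions on each side. A base was called above or below background when its interval excluded the background share and it lay outside all of 1000 random sets, each taking 1 outermost position per site. For the consensus, the random sets read the same sequences at shifts of at least 3 nt from the listed position. For pairs of bases across the 3' end, the background was the mean share over neighbouring outermost positions, without random sets. Differences between organisms have Newcombe intervals. For start codons, triplets ATG, GTG and TTG were looked for in each sequence at a given distance (register) from the listed base. The first listed site of a gene was compared with its later sites, whose share gives the chance level, and with 1000 draws of 1 later site per gene. The fold divides the excess by the site density from 100 nt after the first site. A Shine-Dalgarno stretch was AGGA, GGAG, GAGG or AAGG, 4 to 10 nt ahead of the triplet. Reading frames were taken from the frame free of stop codons across the sequences of a gene. The register named for each organism was chosen as that with the most excess after all were seen.

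Site density was the number of sites less 1 over the distance from first to last site, for genes with at least 5 sites, and intervals are exact Poisson. It replaces density per gene length, which needs gene coordinates. Gene groups were compared with 10000 random lists of the same size drawn from the same 5 classes of span. The groups were fixed before the data were examined, as were the main tests, the first set of other settings and the rule for named genes. The start codon test and the match on span were not run in their planned forms. Those used positions relative to the start codon and gene length, which need gene coordinates. The spacing and codon analyses, the list threshold and the added alternatives were not. The threshold for a group was percentile 97.5, set after a first look at the percentiles. By the rule, the text names per organism the 10 genes with most sites, the 10 densest among those with at least 5 sites and a span of 300 nt or more, up to 10 genes of the fixed groups with a start codon site (the register with U of AUG at -1), and the listed peptide leaders with a site. Members named as examples of a group were chosen after their values were seen. Spacing was compared with 100 sets in which the sites of each gene were scattered evenly over its span.

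The steps were tested on simulated lists of the same size, 2668 genes with 19960 sites for E. coli and 2030 loci with 9987 sites for B. subtilis. Planted pairs 11 nt apart were recovered at 95.3% and 101%, and the reading frame was right in 1416 of 1416 and 975 of 975 cases. The simulated genes held no stop codon in frame, so an assigned frame could not be wrong, and these counts do not test the frame calls. Planted start sites were recovered at 131% in the E. coli simulation and 116% in the B. subtilis simulation with all 3 triplets, and at 112% and 110% with ATG, so the start excess can be overestimated. The largest excess in a register without planted sites was 43.2 and 41.4 genes with all 3 triplets, and 43.1 and 30.1 with ATG. With start sites planted, 5 and 9 of 72 unplanted base combinations were called, and 0 of 72 without them. Of 200 random gene lists per organism, 2 and 5 passed the threshold, and a list with doubled sites stood at percentile 100. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The alternatives covered the background, repeated sequences, weighting of genes, the consensus definition, start windows and gene body, overlapping genes, span matching and minimum site numbers.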

Results

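Nascent elongating transcript sequencing (NET-seq) reads the 3' ends of RNA still held by purified RNA polymerase, so that a pile-up of ends marks a position where the enzyme dwelt. The series held 8 samples, and lists of pause sites were analysed here for 2 of them, wild-type Escherichia coli MG1655 and wild-type Bacillus subtilis 168. The other 6 samples were not analysed here. Each organism had 1 library, so there was no replicate, intervals cover the number of sites only, and no p-value was computed across genes. Each listed site carried a gene symbol, a strand, a genome position, a score and 30 nt of sequence. The E. coli list held 19960 entries under 2668 gene symbols, with a median score of 14 and a range of 2 to 766. The B. subtilis list held 9989 entries under 2021 symbols, with a median score of 15 and a range of 2 to 1757. The number of reads behind a site is unknown, so no read-counting error could be given. Position -1 is the listed base, taken as the RNA 3' end, and +1 is the next base to be added.

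The first question was which bases surrounded the sites. In E. coli, RNA polymerase was found most often after a pyrimidine and before a G. C stood at -1 in 53.8% of sites (95% interval 53.1 to 54.5) against a background of 26.5%, and T in 32.8% against 23.4%. G stood at +1 in 65.3% of sites (64.7 to 66.0) against 29.4%. Further upstream, G was raised at -10 (55.5%), -11 (48.0%) and -2 (53.6%), and T was raised at -3 (45.2% against 23.4%). Purines were scarce at the RNA 3' end, with G at -1 in 5.36% of sites and A in 8.06%. The most frequent pair of bases across the 3' end was C then G, in 41.7% of sites against 9.07% for neighbouring outermost positions. It was followed by T then G in 20.5%. Of 96 base and position combinations tested, 37 lay above and 50 below background, outside both the exact binomial interval and all 1000 random sets. The background was the outermost 3 positions on each side of the sequences, which lie close to the sites and differ among themselves, with A from 18.7% to 24.5%. The random sets cover sampling only, and 31 of the 37 and 46 of the 50 also lay outside the range of those positions.

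In B. subtilis the pyrimidine at the RNA 3' end was shared, but the next base was A. T stood at -1 in 46.4% of the 9989 sites (45.4 to 47.4) and C in 39.3%, against 25.7% and 19.7%. A stood at +1 in 63.9% (62.9 to 64.8) against 30.4%, while G at +1 was at background, 23.6% against 24.3%. A was also raised at -3, at 52.3% against 30.4%. The upstream G was present at a lower level, at 36.0% at -10 and 35.8% at -11 against 24.3%. It was not confined there, since G was also above background at -9 (32.9%), -7 (31.3%), -5 (31.2%) and -4 (31.9%), among other positions. The most frequent pairs across the 3' end were T then A, in 28.4% of sites, and C then A, in 25.8%. By the same test, 29 combinations lay above and 33 below background, and 29 and 32 of these lay outside the range of the outermost positions.

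**Figure D1:**
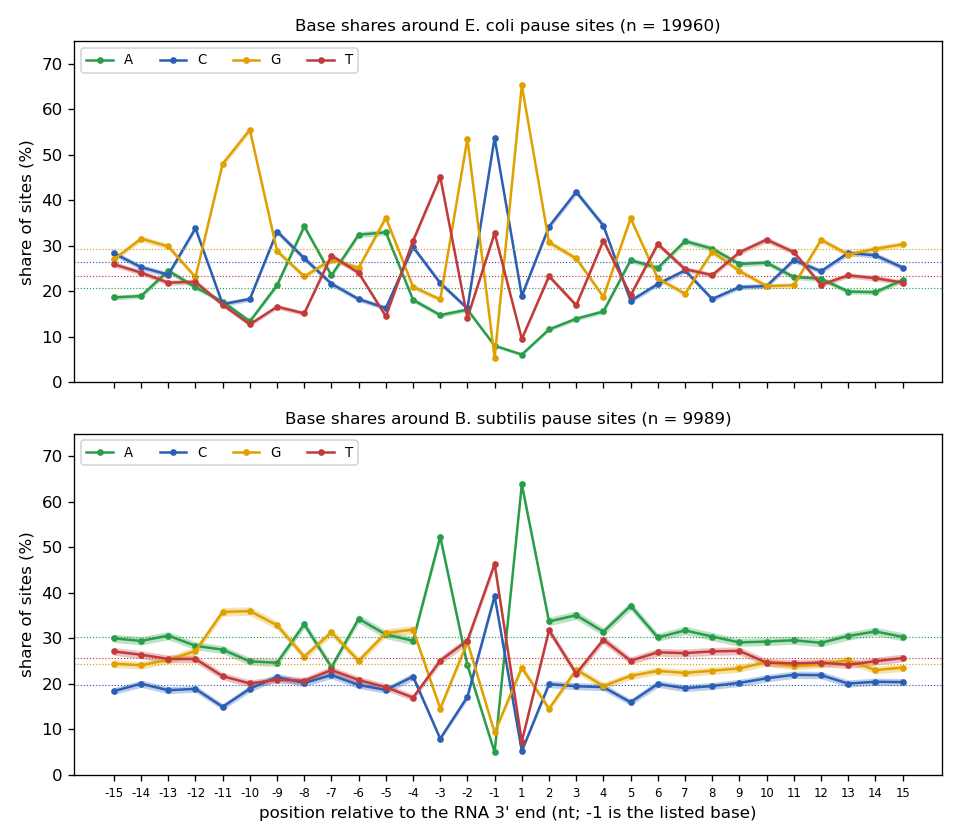
Share of each base (percent of sites) at each position from -15 to 15 nt around the listed RNA 3' end, for E. coli (19960 sites, top) and B. subtilis (9989 sites, bottom); bands are 95% exact binomial intervals and dotted lines the background of each base. G peaks at 1 in E. coli (65.3%) and A in B. subtilis (63.9%).

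The series title names a consensus pause sequence, and G at -10, a pyrimidine at -1 and G at +1 were taken as its form. In E. coli, 6977 of 19960 sites carried all 3 bases, 35.0% (34.3 to 35.6) against 4.38% in random sets, a ratio of 7.97. With G accepted at either -11 or -10 the share was 50.0%, and with G required at both it was 14.7%, ratios of 6.14 and 15.7. In B. subtilis, 911 of 9989 sites carried the consensus, 9.12% (8.56 to 9.70) against 2.44%, a ratio of 3.74. The form with A at +1 instead was carried by 18.1% of the B. subtilis sites (17.4 to 18.9), 7.01 times background, and by 2.46% of the E. coli sites. E. coli sites with higher scores carried the consensus more often, from 29.7% (28.4 to 30.97) in the lowest of 4 score classes to 43.1% (41.7 to 44.5) in the highest. In B. subtilis the lowest class had 9.17% (8.06 to 10.4) and the highest 8.61% (7.54 to 9.78), a difference within the intervals. The classes pooled the sites of all genes, and the score depends on the named gene, so they can sort genes as well as sites. Whether the E. coli trend held within genes was not tested. G at +1 alone was not above background in B. subtilis (23.6%, 22.7 to 24.4).

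The organisms were then compared base by base. A at +1 was far more frequent in B. subtilis, with E. coli minus B. subtilis at -57.8 percentage points (Newcombe 95% interval -58.8 to -56.8). G at +1 was more frequent in E. coli, by 41.8 points (40.7 to 42.8). At -3, A was more frequent in B. subtilis (-37.6 points, -38.7 to -36.5) and T in E. coli (20.1 points, 19.0 to 21.2), and G at -2 was more frequent in E. coli (24.4 points, 23.2 to 25.5). Relative to each organism's own background, 35 of the 96 combinations lay on the same side in both, 13 of them above and 22 below, and 19 lay on opposite sides. Outside the range of the outermost positions in both organisms were 34 of the 35 and 15 of the 19, and in 12 of these 15 the shares themselves differed in the same direction. E. coli grew in rich defined medium with glucose and B. subtilis in LB, so the comparison is between 2 libraries that also differ in medium.

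The series title also places the pause sequence at translation start sites. In E. coli, an excess of pause sites lay at the start codon with the RNA 3' end on the U of AUG and the G next to be added. Among the first listed sites of the 2668 genes, 167 (6.26%) had ATG in that register, against 468 of 17292 later sites (2.71%), which is an excess of 97.4 genes (72.9 to 125). With ATG, GTG and TTG all accepted, the excess was 122 genes (75.5 to 171). Over 1086 genes and with all 3 triplets, the excess was 51.8 genes, against 12.9 expected from the density of sites from 100 nt onward. The excess was thus 4.01 times (1.84 to 6.39) that expectation. It was 2.88 times (1.78 to 4.25) with ATG alone. A Shine-Dalgarno stretch, the ribosome-binding sequence ahead of a start codon, was present with ATG in 68 of the first sites, and 36 of the 37 whose reading frame could be read were in frame, against 16 of 30 for later sites with the same combination. In 1000 draws of a random later site per gene, this combination was found at most 16 times, against 59 among the first sites of the same 2312 genes.

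Genes of several pathways had such a site in E. coli. They included the aminoacyl-tRNA synthetase genes lysS (score 13), serS (23) and pheS (11), and tsf (18), which encodes an elongation factor. The glycolytic gene pgk, for phosphoglycerate kinase, had a site at position 3070643 on the minus strand with a score of 30 and the sequence GAGAGGATTCACCATGTCTGTAATTAAGAT. The protease gene hslU had a site at 4119769 on the minus strand with a score of 64 and the sequence GTAAGGATCTCCCATGTCTGAAATGACCCC. In acnA, for an aconitase of the TCA cycle, the site at 1333856 on the plus strand had a score of 36 and the sequence TTAAGGAGGAGCTATGTCGTCAACCCTACG. The rule also named lysC (an aspartate kinase, score 56), rpmB (a ribosomal protein, 29) and murB (cell wall synthesis, 11). In murB the ATG was out of the reading frame, the only such case of the 37, so its site is not at the start codon, and the frame of acnA and rpmB could not be read. The register was chosen as the one with the most excess, and start codons were read from the sequences, not from an annotation. The fold was 2.20 (1.51 to 3.17) with ATG and a Shine-Dalgarno stretch required, an alternative chosen after the data were seen. It fell below 1 in windows of 5 nt (0.522, 0.147 to 0.964) and 10 nt (0.274, 0.0190 to 0.581) on each side of the start. These windows count only the first site of a gene, and whether that accounts for the values below 1 was not tested.

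In B. subtilis the largest start codon excess lay 2 nt further upstream, with the A of AUG next to be added. There, 139 of 2030 first sites (6.85%) had ATG, against 417 of 7959 later sites (5.24%), an excess of 34.4 genes (10.0 to 61.7). Over 492 genes and with all 3 triplets accepted, the excess was 18.8 genes, against 4.89 expected from the density from 100 nt onward. The excess was thus 3.85 times (1.08 to 7.23) that expectation. With ATG alone it was 3.58 times (1.16 to 6.65). A Shine-Dalgarno stretch and ATG were found together in 52 first sites, and 35 of the 36 with a readable frame were in frame, against 28 of 55 for later sites. Among the 1511 loci with a later site the number was 51, against at most 24 in 1000 random draws. The combination was not particular to this register, since its excess was clear of 0 at every register from -9 (6.20 genes, lower bound 1.39) to -1 (34.2 genes, lower bound 21.0). ATG alone had an excess of similar size 5 nt ahead of the start triplet (33.6 genes, 16.7 to 53.6), and in simulated lists the largest ATG excess at a position without planted sites was 30.1 genes. At the register used for E. coli, 74 first sites (3.65%) had ATG against 211 later sites (2.65%). With a Shine-Dalgarno stretch there were 27, and 11 of the 15 with a readable frame were in frame. The fixed-list genes among them included clpX, for the ATPase of a protease (score 13), and abrB, a transition-state regulator (24), both in frame. They also included prfB, for a peptide chain release factor (9), whose ATG was out of the frame read from the rest of the gene. Whether the prfB ATG is the start codon was not tested further. With all 3 triplets and the gene body taken from 200 nt the fold was 3.78 (0.854 to 7.42) and no longer clear of 1. The windows of 5 nt (1.11, 0.519 to 1.89) and 10 nt (0.662, 0.238 to 1.23) were not clear of 1 either. Among sites with TG in the triplet, an alternative chosen after the data were seen, the ATG excess was -8.27 genes (-52.0 to 34.3).

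**Figure D2:**
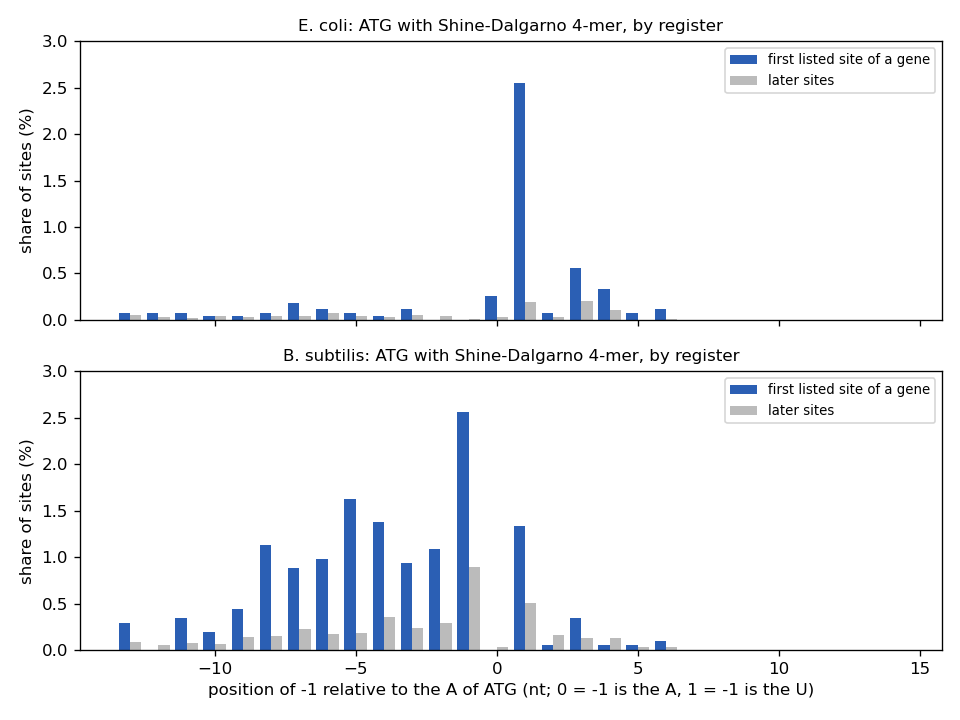
Share of sites (percent) with ATG and a Shine-Dalgarno 4-mer at each distance in nt between the A of ATG and the listed base, for E. coli (top) and B. subtilis (bottom); blue bars are the first listed sites of genes and grey bars later sites. The E. coli bar at 1 reaches 2.55% against 0.191%, and the B. subtilis bar at -1 reaches 2.56% against 0.892%.

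Pause sites were unevenly spread over E. coli genes, with a median of 6 per listed gene and 13.3% of the 2668 genes holding 1 site. The genes for the large RNA polymerase subunits led the list, rpoC with 60 sites (exact Poisson interval 45.8 to 77.2) and rpoB with 51 (37.97 to 67.1). They were followed by cyaA (adenylate cyclase), mukB (a chromosome condensin) and rne (ribonuclease E), with 50 sites each, and dnaE (the replicative DNA polymerase), with 46. The remaining genes among the 10 with most sites were yghJ with 45, bamA (outer membrane protein assembly) with 43, lacZ (beta-galactosidase) with 42 and yhdP with 41. Density was measured between the first and last listed site of a gene, and its median was 12.2 sites per kb over the 1541 genes with at least 5 sites (8.79 and 16.3 at the quartiles). The 10 genes with most sites ranged from 10.2 per kb in yghJ to 19.8 in cyaA, with rpoB at 12.5, so many sites did not mean a high density. The densest gene with at least 5 sites and a span of 300 nt or more was speG, a spermidine acetyltransferase gene. It had 37.5 sites per kb (19.9 to 64.1). It was followed by slmA (nucleoid occlusion) at 35.9, yrdD at 35.4, fabR (a fatty acid synthesis repressor) at 34.2 and rplR (a ribosomal protein) at 34.0. The rest of the 10 densest were tatB (protein export) at 33.6, nudB at 30.9, atpG (an ATP synthase subunit) and luxS (autoinducer synthesis) at 30.6, and ygfB at 30.1. The 14 sites of speG had a median gap of 3 nt, and the Poisson intervals do not allow for such clustering. Of the peptide leaders, short open reading frames ahead of attenuated operons, pyrL had 1 listed site, at 4470523 on the minus strand with a score of 80 and the sequence ATTTTGTCTTACCGCGTCTGAAAAAAGACG.

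In B. subtilis the median was 3 sites per locus, and 25.7% of 2030 loci had 1 site. The gene with most sites was wapA, for a cell wall-associated protein, with 110 (90.4 to 133). The RNA polymerase genes rpoC (71, 55.5 to 89.6) and rpoB (46, 33.7 to 61.4) followed. Next came fusA (an elongation factor) and wprA (a cell wall protease) with 37 sites each, lctP (lactate permease) with 34 and sucA (TCA cycle) with 33. The remaining genes of the 10 were pgm (phosphoglycerate mutase) and srfAA (surfactin synthetase) with 32 each and manP (mannose uptake) with 29. The median density was 10.0 sites per kb over 751 loci. The 10 genes with most sites ranged from 2.90 per kb (1.97 to 4.11) in srfAA to 20.3 in pgm. Among loci with at least 5 sites and a span of 300 nt or more, ribosomal protein genes made up 5 of the 10 densest. They were rplO at 37.7 (20.1 to 64.4), rpsG at 36.4, rplQ at 32.9, rplK at 32.6 and rplC at 26.5. The others were xkdJ (a prophage gene) at 30.9, ndk (nucleoside diphosphate kinase) at 28.5, yqxD at 27.4, adk (adenylate kinase) at 26.8 and ylbN at 25.9. The sites of ndk had a median gap of 3 nt. The number of sites a gene can show depends on its reads, which the lists do not give.

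Gene groups fixed beforehand were then compared with random lists of genes of matched span. In E. coli, 6 of 14 groups had a median density above the 97.5th percentile of 10000 random lists, a threshold set after the percentiles were first seen. In both organisms the random lists drew genes singly and were matched neither on operons nor on read depth. Genes transcribed together thus counted as independent, and the percentiles may be too extreme. The cell division and cell wall group stood at percentile 99.9 with a median of 15.8 sites per kb over 20 genes, including ftsL at 23.3 and minD at 23.2. The flagella and chemotaxis group stood at 99.8 with a median of 15.7 over 24 genes, including cheZ at 23.5 and flhD at 23.4. The aminoacyl-tRNA synthetases stood at 99.2 (median 12.9, 23 genes, glnS at 17.8), and the peptide leaders and attenuated or riboswitch-controlled operons at 99.2 (15.4, 13 genes, hisG at 23.8). RNA polymerase and its factors stood at 98.6 (15.5, 13 genes, rfaH at 33.5) and translation factors at 97.9 (15.2, 11 genes, frr at 19.4). Groups below the threshold were outer membrane porins and lipoproteins (96.4), TCA cycle (93.8), ATP synthase (89.1), ribosomal proteins (85.6), purine and pyrimidine biosynthesis (77.8), chaperones and proteases (75.8), the lactose operon (67.9) and glycolysis with pyruvate dehydrogenase (31.1). Without the match on span, 3 groups passed, namely cell division (98.6), flagella (99.0) and the ribosomal proteins (100, median 21.4). The other 4 groups then lost their call, the aminoacyl-tRNA synthetases at 69.9, translation factors at 90.8, attenuated operons at 94.2 and RNA polymerase at 94.3.

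In B. subtilis, 2 of 13 groups passed the threshold. The ribosomal proteins stood at percentile 99.9, with a median of 24.6 sites per kb over 31 genes against 15.8 in random lists, including rplJ at 64.1 and rpsG at 36.4. Glycolysis and pyruvate dehydrogenase stood at 100, with a median of 14.5 over 13 genes against 8.08, including pgk at 21.7, pdhA at 21.1 and pgm at 20.3. RNA polymerase and its factors (96.2), ATP synthase (92.6), chaperones and proteases (89.1), translation factors (83.3), TCA cycle (80.4) and aminoacyl-tRNA synthetases (65.1) did not pass. Neither did cell division and cell wall (58.3), attenuated or riboswitch-controlled operons (53.0), purine and pyrimidine biosynthesis (37.3), flagella and chemotaxis (21.1) or sporulation and competence (17.7). Without the match on span only the ribosomal proteins passed, and glycolysis stood at 97.3. Whether a group differed between the organisms was not tested.

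Genes with the same symbol in both organisms were compared next, as a description across genes, which are not independent replicates. Of 588 shared symbols, 471 had at least 2 sites in each list, and their densities correlated with a Spearman rho of 0.286 and a Pearson r of 0.265 on log2 values. Permuted pairings gave rho from -0.0892 to 0.0895 in 95% of draws. Among the 267 genes with at least 5 sites in each list, rho was 0.402. No match on span was made here, unlike for the gene groups. Random E. coli lists matched to the spans of the ribosomal proteins had a median of 18.9 sites per kb, against 12.2 unmatched. Whether similar spans account for the correlation was not tested.

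Within genes, E. coli sites were spaced at a preferred distance. Pairs of sites 11 nt apart numbered 1229, in 847 genes, against 215 for the same numbers of sites scattered evenly, a ratio of 5.71 (5.40 to 6.04). Pairs 10 nt apart numbered 426 and pairs 12 nt apart 526. B. subtilis had 85 pairs at 11 nt against 82.6 for scattered sites. Both organisms had many sites next to each other, and 21.5% of the E. coli and 19.0% of the B. subtilis sites had another within 5 nt. The spacing was examined after the lists had been seen.

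**Figure D3:**
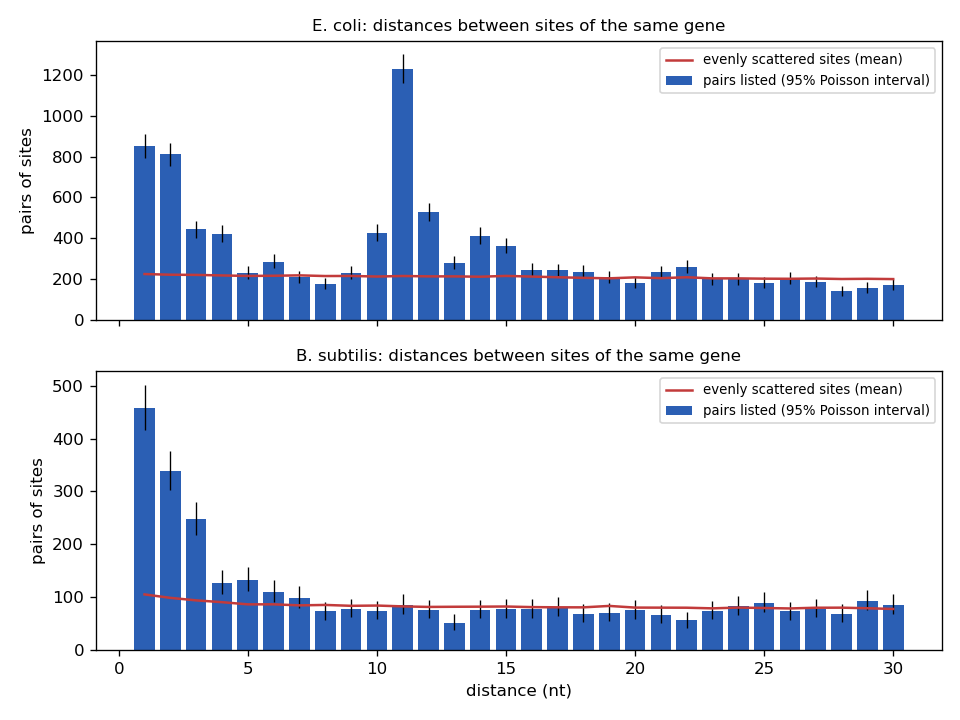
Number of pairs of sites in the same gene at each distance from 1 to 30 nt, for E. coli (top) and B. subtilis (bottom); bars are listed pairs with 95% Poisson intervals and the line is the mean of 100 sets of evenly scattered sites. E. coli has 1229 pairs at 11 nt, and B. subtilis has 85.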

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

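The test of a shifted list position was chosen only after the result was seen. At 19 base and position combinations, E. coli lay on one side of its background and B. subtilis on the other. The difference was not tested across replicates, since each organism had 1 library. The value is the log2 ratio over background in E. coli minus that in B. subtilis. Around the RNA 3' end these were A at +1 (-2.83), A at -3 (-1.27), T at -4 (1.01), A at +2 (-0.98), T at -2 (-0.92), G at -4 (-0.88), G at +2 (0.81) and A at +3 (-0.78). Upstream they were A at -7 (0.54), G at -12 (-0.51), G at -7 (-0.49), C at -7 (-0.45), G at -8 (-0.43) and T at -7 (0.41). Downstream they were G at +5 (0.45), C at +10 (-0.43), A at +9 (0.39), C at +12 (-0.27) and A at +12 (0.20). For A at -7, G at +2, and A and C at +12, the E. coli share lay within the range of the 6 background positions themselves, so these 4 are not distinct from the background, and 15 of the 19 lay outside that range in both organisms. The opposite sides can come from the differing backgrounds alone: the shares themselves were not clearly different for A at -7 (-0.164 points, -1.19 to 0.851), C at -7 (-0.276, -1.27 to 0.711) and C at +10 (-0.0610, -1.05 to 0.915), and differed in the other direction for A at +9 (-3.12), A at +12 (-6.25) and C at +12 (2.49). Both outside that range and with shares differing in the same direction were 12 of the 19.

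A at +1 in B. subtilis was weighed against 3 technical explanations. A few genes with many sites are argued against by the A share at +1, which was 2.03 times background with every locus weighted equally. A shifted list is argued against because the profiles of the organisms correlated best without a shift (r = 0.428, highest of 9 shifts, and in 100 of 100 resamplings). RNA cleaved between a pyrimidine and A would carry no upstream pause element. Of such sites, 55.8% (54.5 to 57.2) had G at -11 or -10, against 42.8% at outermost positions. At sites with a pyrimidine before G the share was 66.8%. Over all B. subtilis sites, however, G was also above its 24.3% background at -9 (32.9%), -7 (31.3%), -5 (31.2%) and -4 (31.9%). The test therefore cannot tell a pause element from a wider upstream excess of G, and how many sites came from cleavage stays open. Organism, medium and library differ together, so the species difference stays open as an untested biological explanation.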

How the results depend on the processing

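Tests chosen only after the result was seen were the added alternatives: shares outside the range of the outermost positions, ATG with a Shine-Dalgarno stretch, sites with TG only, equal gene weights for the consensus, distant unlisted positions and pairs without the top genes. Of 108 values under alternatives, 93 kept their side of the threshold, or their size where there was none. Some of these could hardly change. Resampling of genes reused the consensus share itself and gave only a new interval. Counting each sequence once left 19945 of the 19960 E. coli entries. Groups that never passed could still move far, as the B. subtilis aminoacyl-tRNA synthetases did without the match on span (65.1 to 6.30). In E. coli, the number of called base combinations was 87 and ranged from 77 to 90, and in B. subtilis it was 62 and ranged from 52 to 67. Across backgrounds the consensus ratio ranged from 6.47 to 8.12 in E. coli and from 3.06 to 3.74 in B. subtilis; with G at either or both of -11 and -10 it was 6.14 and 15.7, and 3.06 and 7.03. The 5 base differences recomputed between organisms (A and G at +1, A and T at -3, G at -2) kept their sign among genes with the same symbol and as log2 ratios. G at +1 alone was not above background in B. subtilis (23.6%). For the start codon fold, windows of 5 and 10 nt on each side gave 0.522 and 0.274 in E. coli, and 1.11 and 0.662 in B. subtilis. By construction these windows count 1 first site per gene over many registers, which can lower the value. How far it does so was not tested, and both E. coli intervals lay wholly below 1 (upper bounds 0.964 and 0.581). In B. subtilis a gene body from 200 nt gave 3.78 with a lower bound under 1, and the ATG excess among sites with TG was -8.27 genes; the cause was not tested. Without the match on span, 3 E. coli groups and 1 B. subtilis group passed the threshold instead of 6 and 2; the cause was not tested. Not run were the coding genome as background, windows of 20 nt, an upstream intergenic gap, and antisense or intergenic sites, which need a genome or gene coordinates. Sites near start codons were left out by sequence (a start triplet with a Shine-Dalgarno stretch) instead of by distance. The requirement of 5 sites for the start fold moved nothing, since the main value already required it, and all annotated genes served only for the share with a site. Read depth limits which genes could show sites, and the lists do not give it.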

Other observations

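The tests of close pairs of any distance and of the reading frame at start codons were chosen only after the result was seen. The spacing and codon analyses were added once the lists had been seen, and the expectations of their other tests were set before those were run. The lactose operon was listed in glucose medium, where it is known to be repressed, and the labels name no inducer. The gene lacZ had 42 sites, lacY (lactose permease) 15, and lacA and the repressor gene lacI 7 each, with densities of 13.6, 14.6, 11.7 and 10.6 sites per kb. Coverage was counted over the group members named in the E. coli reference gene table only. Every such gene had a site in 8 of the 14 E. coli groups. In 10 of the 14 the interval lay above the 60.2% of all protein-coding genes with a site. It included 60.2% for the TCA cycle (77.8%, 52.4 to 93.6), the porins (90.9%, 58.7 to 99.8), the lactose operon (100%, 39.8 to 100) and the leaders and attenuated operons (55.6%, 38.1 to 72.1).

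In E. coli, sites 11 nt apart were weighed against 3 technical explanations. The G at +1 of the upstream site is the base at -11 of the downstream site, and it was G in 80.6% of pairs (78.3 to 82.8) against 64.3% of sites in no such pair. Supply of the consensus is argued against as the whole cause, since 21.9% of consensus positions 11 nt downstream of a site were listed (20.4 to 23.3) against at most 15.6% at other distances from 5 to 13 nt. A few genes are argued against by the 3.74% of pairs in the 10 genes with most, and close pairs of any distance by the lower bound of 1161 pairs at 11 nt, against upper bounds of 205 at 8 nt and 454 at 14 nt. Supply was itself higher at 11 nt, at 3202 positions against at most 1725, and may account for a part, while the unknown pause caller and a tie between successive pauses stay open, and no biological explanation was tested.

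For sites at the start codon, the share of E. coli first sites with ATG, 6.26% against 2.71% of later sites, is from a register picked on the same values. That the ATG is unrelated to the start codon is argued against, because with a Shine-Dalgarno stretch it was in frame in 97.3% of first sites (85.8 to 99.9) against 53.3% of later sites (34.3 to 71.7). Whether the consensus at start codons alone is enough cannot be told apart from these data. ATG in that register supplies the pyrimidine and the G itself, so that the 60.5% (52.6 to 67.9) with the full consensus measures only G at -10, which was 48.9% (44.3 to 53.6) at later ATG sites. The excess may be partly a property of the estimator, since with ATG, GTG and TTG accepted other registers also had excesses, 82.3 genes at register 3 in E. coli and 46.0 at register -5 in B. subtilis, beside 122 and 46.5 at the peaks. A role of translation was not tested.

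A further hypothesis was that the codon position of E. coli sites may follow the supply of pyrimidine-G positions. The RNA 3' end fell on codon position 1 in 34.4% of sites, 2 in 38.8% and 3 in 26.8%. At the commonest position, 2, listed pyrimidine-G sites lay -2.11 points from unlisted ones (-3.17 to -1.04). At positions 1 and 3 they lay 15.5 and -13.4 points away, which argues against supply of pyrimidine-G positions as the whole cause. The unlisted positions were not required to carry the upstream G, so supply of the full consensus was not tested and stays open.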
